A study of Mus musculus with 6 samples.

How the data were processed

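The series holds 6 RNA-seq libraries of primary mouse astrocytes, 3 labelled human AQP4-IgG and 3 labelled human control IgG, at 24 h. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with a SMARTer mRNA-seq kit. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner, the counting tool and the annotation release are not given in the sources used here, nor whether reads were counted by strand.

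A single deposited table gives 14147 genes with their coordinates, 6 columns of values and the authors' own comparison. Each row has a larger group mean of at least 0.5, so genes below that level were not analysed here. The unit of the 6 columns is not named in the header and was inferred from the values: they are FPKM as deposited by the authors, scaled by exon length and library total, with reads or fragments not stated. Multiplying a value by the union exon length of its gene in GENCODE M21 gave whole multiples of 1 step per library. This held within 0.1 reads for 98.99% to 99.14% of the values under 200 reads in each library, over 13311 genes whose coordinates equal those of M21. The step gave the library totals of 17.9 to 20.6 M reads. The control columns carry the word control, the letters WT in place of the antibody name and a number that matches the labels. The other 3 columns carry a disease abbreviation in place of the antibody name and were taken as AQP4-IgG 1 to 3 because the design has 2 groups, and 0 columns of per-sample values remained unmapped. The deposited log2 fold changes and p-values are the authors' own. Their first adjusted p-value is the unadjusted one times 25034, so their adjustment covered more genes than the rows listed. Over 11555 genes, the deposited log2 fold changes differed by a median of 0.0015 from those of limma-voom with quantile normalization on the recovered reads, and by a median of 0.0159 without quantile normalization. The files do not state which method the authors used.

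The tests were fixed before the data were examined. Because the table holds FPKM and not counts, the main test was limma with a trend and robust variance estimation on log2(FPKM + 1). It was run on genes with a mean of at least 1 FPKM over the 6 libraries, which kept 12334 genes and left out 1813. The Benjamini-Hochberg adjusted p had to be under 0.05. A total of 30 gene lists was fixed beforehand, on interferon, NF-kB, complement, reactive astrocyte, metabolic and stress programs and on markers of other glial, neuronal and vascular cells. The 27 lists with at least 5 tested members were tested with limma's camera with a preset correlation of 0.01, with adjustment over the lists. Counts of members past the gene test are given over all genes and adjusted over the list alone. Some genes stand in several lists: 5 of the 23 tested microglia markers also stand in another list, as do 6 of the 12 A1 genes.

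The genes named were set by a rule fixed beforehand. It takes the 8 largest rises and the 8 largest falls among genes past the threshold whose groups do not overlap, leaving out clone, predicted-gene and pseudogene names. It adds the up to 3 members of each list with the smallest p among those past the threshold, or else the 1 with the smallest p. It always includes Aqp4, Gfap, Slc1a2, C3, Lcn2, Il6, Ccl2 and Cxcl10 where measured. The rule gave 63 genes, of which 46 passed the threshold; 1 of them is not reported here.

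Alternatives fixed beforehand were median scaling, limma without a trend, no filter, a mean of at least 10 FPKM, a pseudocount of 0.1, the replicate number as a block and leaving out each library. For the lists they were an estimated correlation and the fry test. Added after the data were seen were limma-voom on the recovered reads, limma without robust variance estimation, limma-voom with quantile normalization and without robust variance, and the similarity of libraries under other settings. Recovered reads exist only for genes whose coordinates equal those of M21, so Aqp4 was outside the limma-voom fits. All 10 splits of the 6 libraries into 3 and 3 were refitted. With 3 against 3 an exact permutation test of a single value cannot give a p under 0.1, so none was used.

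Libraries of a group were compared before they were averaged: the chi-square of recovered reads per gene between pairs ranged from 3.82 to 7.06, so no pair agreed within sampling noise. The scripts were tested on simulated data built from these libraries, with the same dispersion of 0.00177 for every gene. With 11567 genes fitted, the main test recovered 66% of genes changed 1.25-fold, 94% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 10 false calls among 188. A simulated list that moved was called and 0 of 20 lists that did not move were. Simulated genes were drawn independently, so this check cannot show how camera fares where the members of a list vary together. In the real libraries the estimated correlation was 0.664 for the interferon list and 0.773 for the microglia list. Transcript sequences of GENCODE M21 were searched for 50-base stretches shared between genes. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.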

Results

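RNA sequencing measured transcript levels in cultured primary mouse astrocytes, the glial cells that surround synapses and blood vessels in the brain. The labels give the treatment as human IgG directed against aquaporin-4 (AQP4-IgG) or a human control IgG (Control-IgG) and the time as 24 h. The series title also mentions conditioned medium, so it is open whether the IgG reached these cells directly or in such medium. Aquaporin-4 is the main water channel of astrocytes, and antibodies against it are the serum marker of neuromyelitis optica. The labels give 3 libraries per group, numbered 1 to 3, and describe the cells as wild type. The values are FPKM (fragments or reads scaled by exon length and library total) for 14147 listed genes. Whole reads recovered from these values put the library totals at 20.5, 20.4 and 20.6 M reads in AQP4-IgG libraries 1 to 3. The Control-IgG libraries held 20.3, 17.9 and 20.1 M reads. At this depth 1 read in a gene with 1 kb of exon is worth between 0.0485 and 0.0558 FPKM. Values below are means ± SD in FPKM with n = 3 libraries per group, and adjusted p-values are from limma over 12334 genes unless another source is named. Fold changes on the log2 scale are of log2(FPKM + 1), which understates the change of genes with low levels. The labels do not say whether the libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

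The transcript of the antibody's target was slightly more abundant with AQP4-IgG. Aqp4 (ENSMUSG00000024411, minus strand of chromosome 18, 15389394 to 15403684 in GRCm38) averaged 130 ± 2.48 FPKM with AQP4-IgG and 104 ± 7.67 FPKM with Control-IgG, 1.26-fold higher. All 3 AQP4-IgG libraries lay above all 3 Control-IgG libraries, with a log2 fold change of 0.33 (SE 0.054, adjusted p = 0.0216). The call did not hold without the trend in limma (adjusted p = 0.0611). It also ended when any of 5 libraries was left out, with adjusted p of 0.0983, 0.107 and 0.0502 without AQP4-IgG 1, 2 and 3, and of 0.0667 and 0.0863 without Control-IgG 2 and 3.

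The comparison of the groups asks which transcripts differ between astrocyte cultures given AQP4-IgG and astrocyte cultures given control IgG. Myeloid transcripts were also present in both groups, and in which cells a change arose was not tested. With AQP4-IgG, interferon-stimulated genes rose together, by 1.72- to 5.05-fold for the 9 named members that passed. Some chemokines, the immunoproteasome subunits Psmb8, Psmb9 and Psmb10 and the complement proteases C1s1 and C1ra also rose. The largest rise on the log2(FPKM + 1) scale was that of the chemokine Ccl6, from 3.84 ± 0.423 to 20.9 ± 1.31 FPKM. The largest fall on that scale was smaller, that of Fam107a, an actin-associated stress-response gene, from 24.97 ± 3.25 to 12.4 ± 0.912 FPKM. By the ratio of group means Arl4d fell more, 2.09-fold against 2.02-fold. Transcripts of the astrocyte glutamate transporters Slc1a3 and Slc1a2 rose by 1.26- and 1.34-fold, while Gfap averaged 84.1 ± 6.97 FPKM against 77.7 ± 8.29 FPKM (log2 fold change 0.11, adjusted p = 0.686). In all, 258 genes passed an adjusted p of 0.05, 180 higher and 78 lower with AQP4-IgG, and 1643 had an unadjusted p under 0.05. The ratio of group means reached 2 in 45 of the 180 and in 3 of the 78. In each of the 258 genes the libraries of the groups did not overlap, as was the case for 2346 genes (19% of those tested, where chance gives 10%). The count depended on single libraries: it was 78, 66 and 172 without AQP4-IgG 1, 2 and 3, and 390, 55 and 117 without Control-IgG 1, 2 and 3. Of the 46 named genes past the threshold, 17 kept their call in each of these 6 fits. Another 19 kept it in at most 2 of them: Il33 in 0, Aqp4, Casp12, Ifit1, Slc1a2 and Steap4 in 1, and Acta2, C1ra, Cp, Cx3cl1, Cx3cr1, Ifit3, Ndufa1, Oasl2, Psmb9, S100a7a, Slc1a3, Socs3 and Timp1 in 2.

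**Figure D1:**
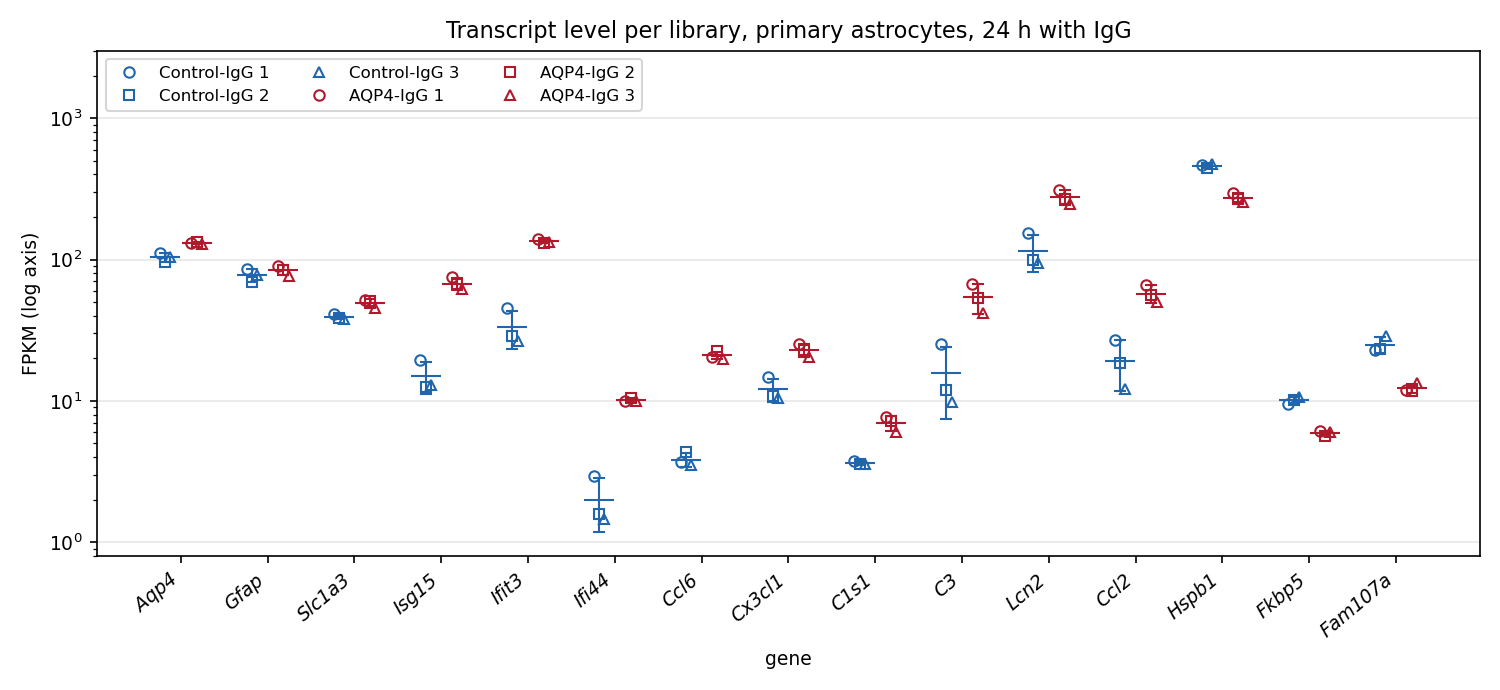
FPKM on a log axis of 15 genes in each library, with open symbols for libraries 1 to 3 (Control-IgG blue, AQP4-IgG red) and horizontal bars with whiskers for the mean and SD. Isg15, Ifit3, Ifi44 and Ccl6 lie several-fold higher in all 3 AQP4-IgG libraries, Hspb1, Fkbp5 and Fam107a lie lower, and the Gfap values of the groups overlap.

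The interferon-stimulated genes formed the list with the highest median change. Of 34 measured members, 27 rose, 0 fell and 7 did not pass the test, and adjusted over the list alone 33 rose. The median log2 fold change was 1.05, with quartiles of 0.75 and 1.59. In 33 members every AQP4-IgG library exceeded every Control-IgG library. The exception was Ifit2 (log2 fold change 0.11, adjusted p = 0.458), singled out after its values were seen. Isg15, a ubiquitin-like modifier on chromosome 4 (156199424 to 156200818, minus strand), rose 4.52-fold from 14.95 ± 3.83 to 67.6 ± 6.64 FPKM (adjusted p = 0.00874). Ifi44 rose 5.05-fold to 10.1 ± 0.322 FPKM (adjusted p = 0.00592), and Oasl2, a relative of the antiviral oligoadenylate synthetases, rose 3.88-fold to 28.1 ± 2.34 FPKM (adjusted p = 0.0326). Among the IFIT genes, Ifit1, whose protein binds viral RNA, rose 3.49-fold from 14.6 ± 4.74 to 51.0 ± 2.95 FPKM (adjusted p = 0.0243). Ifit3 rose 4.02-fold to 134 ± 4.41 FPKM and Ifit3b 4.86-fold to 21.2 ± 2.13 FPKM, with adjusted p of 0.016 and 0.00435. Of the 50-base stretches of Ifit3 and Ifit3b, 51.2% and 45% also occur in transcripts of other genes, mostly in each other, so the split of reads between this pair is uncertain. The smallest p-values in the list belonged to Parp14 and Parp9, members of the ADP-ribosyltransferase family, and to the interferon-inducible GTPase Iigp1. These rose 1.78-, 1.72- and 4.78-fold, with adjusted p of 0.00171, 0.00418 and 0.00435. The list moved against the other genes in limma's camera test with a preset correlation (adjusted p = 4.71e-49). With a correlation estimated from these libraries its adjusted p = 0.304, and in the fry test of movement in 1 direction its adjusted p = 0.0327.

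Several libraries differed in the level of this list within a group. Relative to the Control-IgG mean, its members averaged 1.27, 1.14 and 1.06 log2 units in AQP4-IgG 1, 2 and 3, and 0.29, -0.09 and -0.20 in Control-IgG 1, 2 and 3. Control-IgG 1 thus lay above the other control libraries, as it also did for the antigen presentation, NF-kB and microglia lists. It was the highest control library for non-immune lists too, such as astrocyte markers (0.061), unfolded protein response (0.086) and NRF2 (0.096). For the cell cycle, fibroblast and mitochondrially encoded lists it was not. The number of interferon-stimulated genes past the test was 14 without AQP4-IgG 1, 11 without AQP4-IgG 2 and 11 without Control-IgG 2, and 0 members fell in any of these fits.

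**Figure D2:**
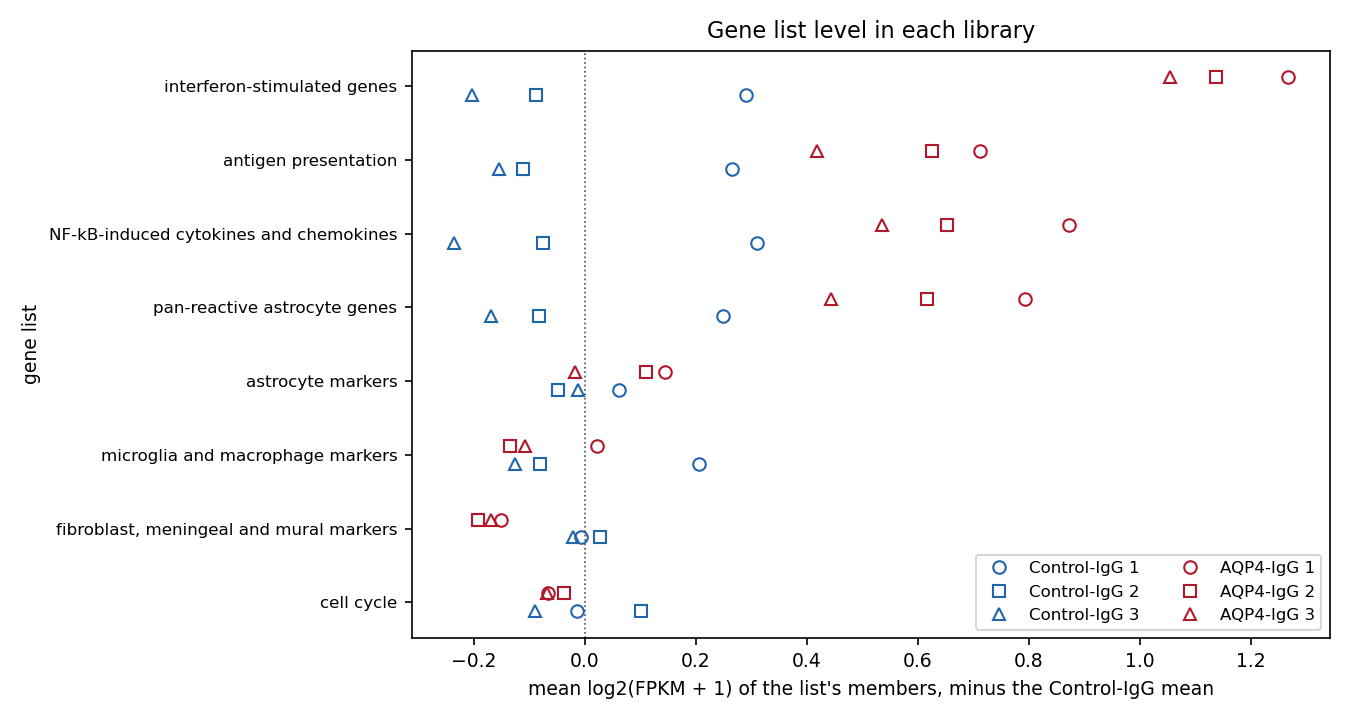
Mean log2(FPKM + 1) of the members of 8 gene lists in each library (horizontal axis, minus the mean of the Control-IgG libraries), with Control-IgG in blue and AQP4-IgG in red and a symbol for each library number. For the interferon-stimulated genes the AQP4-IgG libraries lie between 1.06 and 1.27 and the Control-IgG libraries between -0.20 and 0.29, and Control-IgG 1 is the highest control library for the upper 6 lists.

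Some chemokine and cytokine genes induced by NF-kB were higher with AQP4-IgG. Of 29 measured members, 5 rose, 0 fell and 24 did not pass the test, and adjusted over the list alone 17 rose. The membrane-bound chemokines Cxcl16 and Cx3cl1 rose from 5.82 ± 0.897 to 10.5 ± 0.977 FPKM and from 12.1 ± 2.32 to 22.9 ± 2.51 FPKM, with adjusted p of 0.0106 and 0.0304. The alarmin Il33 rose from 1.29 ± 0.132 to 2.02 ± 0.084 FPKM (adjusted p = 0.038), a call that held in 7 of 14 alternative fits (adjusted p up to 0.157). The other members past the test, named after their values were seen, were the adhesion molecule Icam1 (2.01-fold, adjusted p = 0.0403) and the cytokine Il1a (2.62-fold, adjusted p = 0.0408). Ccl2, a monocyte chemoattractant, averaged 57.4 ± 8.39 FPKM with AQP4-IgG and 19.3 ± 7.54 FPKM with Control-IgG (log2 fold change 1.58, adjusted p = 0.107). Cxcl10, a chemokine for activated T cells, averaged 6.74 ± 3.57 and 1.63 ± 1.28 FPKM (log2 fold change 1.59, adjusted p = 0.293). Both lay higher in all 3 AQP4-IgG libraries than in any control library. Il6 was not analysed here. The median log2 fold change of the list was 0.47 (adjusted p = 1.75e-17 with camera, adjusted p = 0.531 with an estimated correlation). The count of 5 was 11 in limma without robust variance estimation and 16 with the replicate number as a block. Limma-voom with quantile normalization gave 12, and a pseudocount of 0.1 gave 4. The count was 1, 1 and 3 without AQP4-IgG 1, 2 and 3, and 14, 0 and 1 without Control-IgG 1, 2 and 3.

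Some genes of antigen presentation were higher too. Of 16 measured members, 5 rose, 0 fell and 11 did not pass the test, and 12 rose adjusted over the list alone. The immunoproteasome subunits Psmb8, Psmb9 and Psmb10, which replace the constitutive catalytic subunits when peptides are made for class I molecules, rose 2.15-, 1.97- and 1.62-fold with adjusted p of 0.0118, 0.0207 and 0.00822. Psmb10, the most abundant of them, rose from 16.1 ± 1.4 to 26.0 ± 2.42 FPKM. The median log2 fold change of the list was 0.54 (adjusted p = 1.88e-13 with camera, adjusted p = 0.531 with an estimated correlation). The class I gene H2-K1 averaged 117 ± 18.0 FPKM against 69.6 ± 20.7 FPKM (adjusted p = 0.259) and was looked up after the list was seen. The count of 5 was 1, 1 and 4 without AQP4-IgG 1, 2 and 3, and 9, 0 and 2 without Control-IgG 1, 2 and 3.

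Among 17 complement genes, 2 rose, 0 fell and 15 did not pass the test; adjusted over the list alone, 6 rose and 2 fell. The classical-pathway proteases C1s1 and C1ra rose from 3.64 ± 0.098 to 6.99 ± 0.844 FPKM and from 8.59 ± 1.05 to 12.9 ± 1.3 FPKM, with adjusted p of 0.00435 and 0.0264. Of their 50-base stretches, 21.8% and 50.8% occur in the neighbouring copies C1s2 and C1rb or another gene, so their levels are uncertain to that extent. C3, the central complement component and a marker of neurotoxic reactive astrocytes, averaged 54.1 ± 13.1 FPKM with AQP4-IgG and 15.6 ± 8.22 FPKM with Control-IgG. Its groups did not overlap and its log2 fold change was 1.81 (SE 0.397), but its adjusted p was 0.139 in the main limma fit. Without robust variance estimation limma gave an adjusted p of 0.0307. The complement list had a median log2 fold change of 0.03 and did not pass (adjusted p = 0.238).

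Markers of reactive astrocytes moved in a mixed way. Of 12 pan-reactive genes, 3 rose, 1 fell and 8 did not pass the test, with 9 higher and 1 lower adjusted over the list alone. The ferroxidase ceruloplasmin (Cp) rose from 58.3 ± 10.4 to 107 ± 6.76 FPKM and the protease inhibitor Timp1 from 86.4 ± 4.92 to 111 ± 7.69 FPKM, both with adjusted p = 0.0243. The metalloreductase Steap4 rose 6.79-fold from 1.07 ± 0.804 to 7.25 ± 1.84 FPKM (adjusted p = 0.0471), a call that held in 7 of 14 alternative fits (adjusted p up to 0.186). The small heat-shock protein gene Hspb1 fell from 461 ± 13.2 to 275 ± 20.7 FPKM (adjusted p = 0.0016), with 48.8% of its 50-base stretches also found in a pseudogene. Lcn2, which encodes the secreted iron-carrier protein lipocalin-2, averaged 275 ± 32.6 against 115 ± 33.1 FPKM (log2 fold change 1.28, adjusted p = 0.0681). The list had a median log2 fold change of 0.50 (adjusted p = 6.08e-06 with camera, adjusted p = 0.531 with an estimated correlation). Of 12 A1 genes, the set first described after inflammatory stimulation, 4 rose, 1 fell and 7 did not pass (7 and 1 adjusted over the list alone). Iigp1 and Psmb8 were among the former, and Fkbp5, a co-chaperone of steroid receptors, fell from 10.1 ± 0.526 to 5.92 ± 0.235 FPKM (adjusted p = 0.00223). The A1 list had a median log2 fold change of 0.49 (adjusted p = 4.57e-05 with camera, adjusted p = 0.531 with an estimated correlation). Of 11 A2 genes, 1 rose, 0 fell and 10 did not pass; adjusted over the list alone, 4 rose and 1 fell. The A2 gene that rose was the tetraspanin-like membrane protein gene Tm4sf1 (1.38-fold, adjusted p = 0.0106), and the A2 list did not pass (adjusted p = 0.126).

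The calls of C3, Lcn2, Ccl2 and Cxcl10 differed between fits. With robust variance estimation turned off, an alternative chosen after the data were seen, limma gave adjusted p of 0.0307, 0.014 and 0.0193 for C3, Lcn2 and Ccl2, which then passed, and 0.115 for Cxcl10. Limma-voom on recovered reads called 0 of them (adjusted p of 0.147, 0.0856, 0.0934 and 0.403 in this order). With quantile normalization and without robust variance estimation limma-voom called all 4 (adjusted p of 0.000965, 0.000224, 0.000357 and 0.0349). Limma without the trend called Lcn2 alone (adjusted p = 0.0468). Without Control-IgG 1, C3, Lcn2 and Ccl2 passed (adjusted p of 0.0303, 0.000677 and 0.043) and Cxcl10 did not (adjusted p = 0.213), and 0 of the 4 passed without any other single library. In the authors' deposited table their adjusted p-values are 0.00141, 0.000242, 0.000594 and 0.0621.

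**Figure D3:**
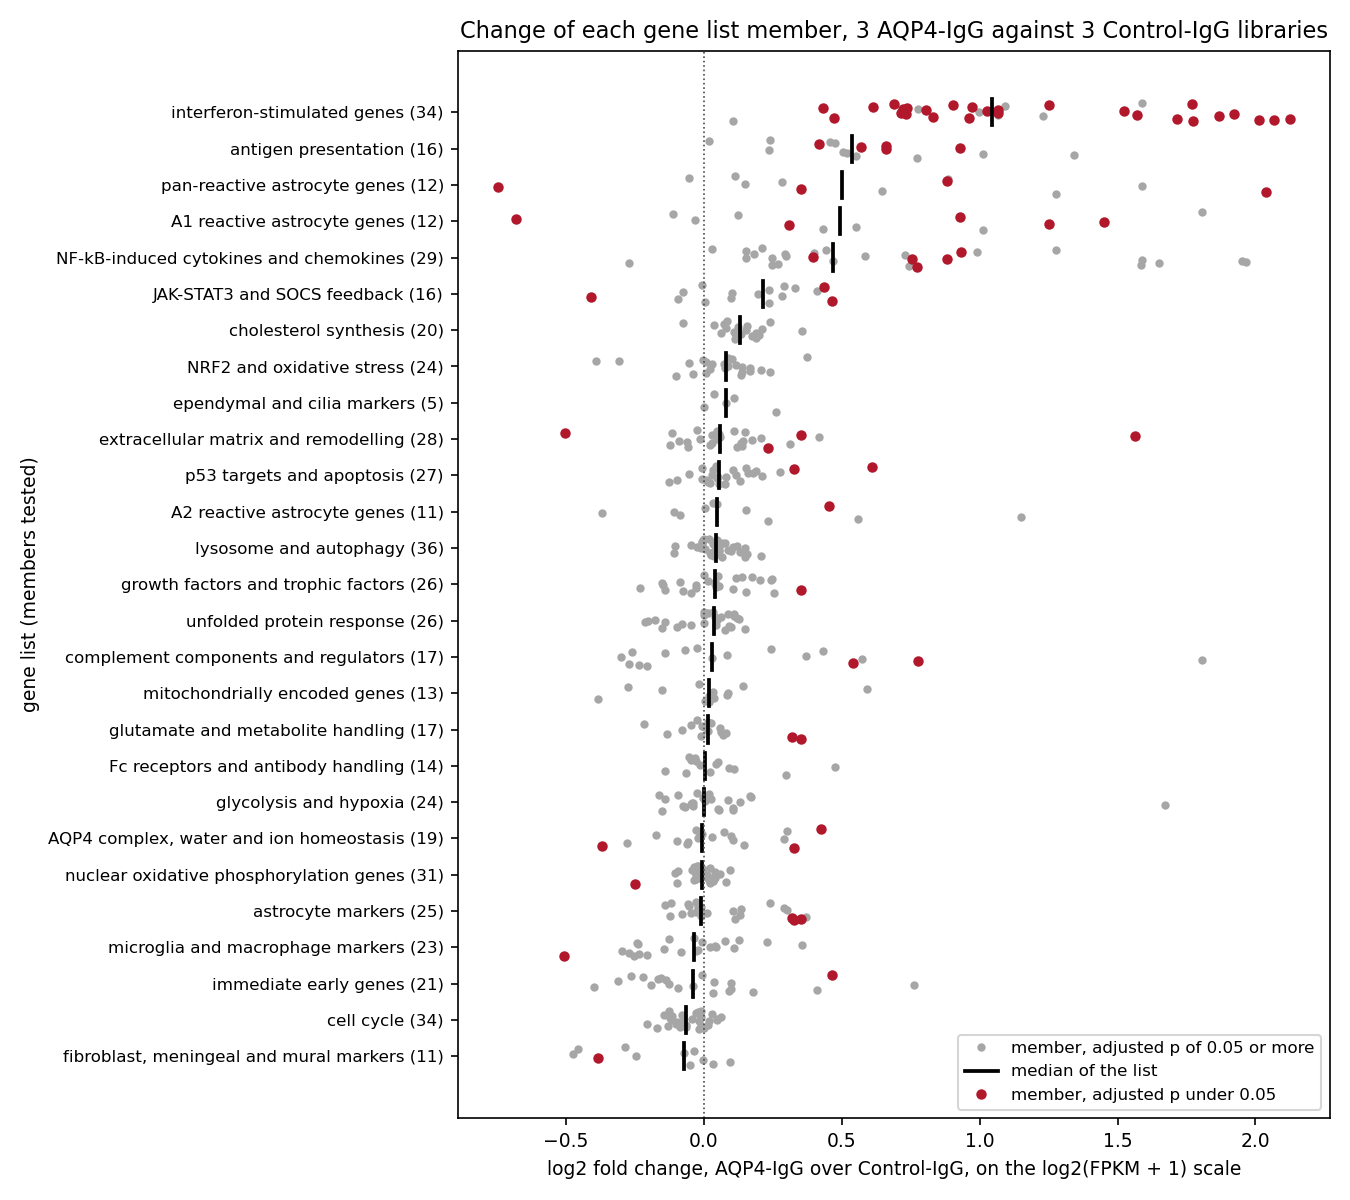
Log2 fold change (AQP4-IgG over Control-IgG, log2(FPKM + 1) scale, horizontal axis) of each tested member of the 27 gene lists with at least 5 tested members, ordered by median (black bars), with members past an adjusted p of 0.05 in red and the others in grey. The interferon-stimulated genes stand at a median of 1.05, and the lists at the bottom, cell cycle and fibroblast, meningeal and mural markers, at -0.07.

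Astrocyte identity genes varied little as a group. Of 25 astrocyte markers, 3 rose (Aqp4, Slc1a3 and Slc1a2), 0 fell and 22 did not pass the test, and 7 rose adjusted over the list alone. Slc1a3, the transporter GLAST, averaged 49.3 ± 3.61 against 39.3 ± 1.43 FPKM (adjusted p = 0.0304), and Slc1a2, the transporter GLT-1, 6.63 ± 0.655 against 4.97 ± 0.172 FPKM (adjusted p = 0.0464). Both calls depended on the fit: that of Slc1a3 held in 10 of 15 alternative fits, 2 of them among the 6 with 1 library left out, and that of Slc1a2 in 6 of 14, 1 of them with a library left out. The highest adjusted p in these fits was 0.142 for Slc1a3 and 0.167 for Slc1a2. The astrocyte marker list did not pass (median log2 fold change -0.01, mean 0.08, adjusted p = 0.0644 in the upward direction of the mean). The list of glutamate and metabolite handling had 17 members, of which these same transporters rose, 0 fell and 15 did not pass, also adjusted over the list alone (adjusted p = 0.52). Among 19 genes of the AQP4 complex and of water and ion homeostasis, 2 rose, 1 fell and 16 did not pass; adjusted over the list alone, 4 rose and 3 fell. Agrn, the basement membrane proteoglycan agrin, rose from 26.9 ± 1.13 to 36.4 ± 1.53 FPKM (adjusted p = 0.00522). That list did not pass (adjusted p = 0.6).

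Markers of other cells were present at differing levels. Of 23 microglia and macrophage markers, 0 rose, 1 fell and 22 did not pass the test (1 rose and 1 fell adjusted over the list alone). The fractalkine receptor Cx3cr1 fell from 11.9 ± 1.4 to 8.09 ± 0.95 FPKM (adjusted p = 0.0427). Lyz2, an abundant myeloid transcript looked up after the data were seen, averaged 825 ± 55.0 and 833 ± 113 FPKM, so myeloid transcripts were present in both groups. The microglia list had a median log2 fold change of -0.04 and did not pass (adjusted p = 0.104), and 0.21 log2 units separated Control-IgG 1 from the control mean. Of 11 fibroblast, meningeal and mural markers, 0 rose, 1 fell and 10 did not pass, with 5 lower adjusted over the list alone. Smooth-muscle actin Acta2 fell from 2782 ± 147 to 2134 ± 173 FPKM (adjusted p = 0.0243), and the list fell in camera (median -0.07, adjusted p = 0.00195, and adjusted p = 0.304 with an estimated correlation). The negative values came mainly from Acta2, Tagln, Cnn1, Myh11 and Ogn (log2 fold changes -0.245 to -0.474). The members Col1a1, Col1a2, Col3a1, Pdgfrb, Col6a1 and Foxc1 lay between -0.071 and 0.095. The oligodendrocyte, neuron and endothelial lists had 4 tested members each and were not tested as lists. In limma over all genes 0 of their members passed, with 2, 0 and 1 at an unadjusted p under 0.05, and limma-voom on recovered reads called 0 as well. The members with the smallest p were Olig2 (45.5 ± 2.16 against 51.4 ± 2.09 FPKM, adjusted p = 0.137), Map2 (8.13 ± 0.395 against 8.64 ± 0.557 FPKM, adjusted p = 0.682) and Cdh5 (3.54 ± 0.084 against 2.89 ± 0.228 FPKM, adjusted p = 0.162). Adjusted over the list alone, 2 oligodendrocyte genes were lower, 0 neuron genes passed and 1 endothelial gene was higher. Of 5 ependymal and cilia markers 0 passed in limma (1 at an unadjusted p under 0.05 and 1 in limma-voom, 1 higher adjusted over the list alone), Foxj1 averaged 43.8 ± 2.9 against 36.3 ± 2.41 FPKM (adjusted p = 0.0803), and the list did not pass (adjusted p = 0.238).

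Matrix and signalling genes contributed some of the clearest single changes. Of 28 genes of extracellular matrix and remodelling, 3 rose, 1 fell and 24 did not pass; adjusted over the list alone, 6 rose and 1 fell. The matrix metalloproteinase stromelysin-1 (Mmp3) rose 3.91-fold from 2.07 ± 0.288 to 8.08 ± 1.05 FPKM (adjusted p = 0.000796), with 8.4% of its 50-base stretches shared with other genes. The protease Adamts1 fell from 142 ± 9.41 to 100.2 ± 6.37 FPKM (adjusted p = 0.00717). The matrix list rose in camera (median 0.06, adjusted p = 0.0042, and adjusted p = 0.69 with an estimated correlation). Of 16 JAK-STAT3 and SOCS feedback genes, 2 rose, 1 fell and 13 did not pass (7 higher and 1 lower adjusted over the list alone). The cytokine feedback inhibitor Socs3 rose from 10.6 ± 1.06 to 15.0 ± 1.67 FPKM (adjusted p = 0.0487), a call that held in 7 of 15 alternative fits (adjusted p up to 0.182). Fgl2 rose 1.45-fold (adjusted p = 0.0155), and the kinase gene Pim3 fell from 24.1 ± 1.03 to 17.9 ± 0.97 FPKM (adjusted p = 0.00874). Its median was 0.22 (adjusted p = 0.00288 with camera, adjusted p = 0.69 with an estimated correlation). Of 27 p53 and apoptosis genes 2 rose, 0 fell and 25 did not pass, also adjusted over the list alone. They were the necroptosis effector Mlkl, from 3.01 ± 0.361 to 5.12 ± 0.595 FPKM (adjusted p = 0.016), and Casp12, from 10.02 ± 0.626 to 12.8 ± 0.274 FPKM (adjusted p = 0.0208), neither of them a core p53 target. That list rose in camera (median 0.06, adjusted p = 0.00149, and adjusted p = 0.675 with an estimated correlation). Of 26 growth and trophic factors, 1 rose, 0 fell and 25 did not pass (3 higher and 2 lower adjusted over the list alone). The 1 that rose was Fgf2, from 13.6 ± 0.378 to 17.7 ± 0.878 FPKM (adjusted p = 0.0118), and the list did not pass (adjusted p = 0.357). Of 21 immediate early genes, Socs3 alone rose in limma over all genes, 0 fell and 20 did not pass (2 higher and 5 lower adjusted over the list alone, list adjusted p = 0.238).

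The remaining lists held few or no single genes past the test. Of 20 cholesterol synthesis genes, 0 passed and 3 rose adjusted over the list alone, with Hmgcs1 at 29.8 ± 0.544 against 26.0 ± 1.08 FPKM (adjusted p = 0.0715). That list rose in camera (median 0.13, adjusted p = 2.97e-06, and adjusted p = 0.531 with an estimated correlation). Of 34 cell cycle genes 0 passed, also adjusted over the list alone, with Cdc45 at 2.74 ± 0.407 against 3.29 ± 0.094 FPKM (adjusted p = 0.348). The cell cycle list fell in camera (median -0.07, adjusted p = 0.0111, and adjusted p = 0.795 with an estimated correlation). Of 36 lysosome and autophagy genes 0 passed, also adjusted over the list alone, with Lamp2 at 44.8 ± 1.57 against 40.3 ± 0.237 FPKM (adjusted p = 0.117). The lysosome list rose in camera (median 0.04, adjusted p = 0.0321, and adjusted p = 0.827 with an estimated correlation). Of 14 genes of Fc receptors and antibody handling 0 passed and 1 rose adjusted over the list alone, with the cytosolic antibody receptor Trim21 at 5.10 ± 0.808 against 3.37 ± 0.259 FPKM (adjusted p = 0.0502). That list did not pass (adjusted p = 0.512). Of 26 unfolded protein response genes 0 passed, also adjusted over the list alone, with Asns at 55.1 ± 2.47 against 62.3 ± 2.27 FPKM (adjusted p = 0.116, list adjusted p = 0.455). Of 24 NRF2 and oxidative stress genes 0 passed (1 higher and 1 lower adjusted over the list alone), with the metallothionein Mt1 at 355 ± 26.8 against 440 ± 26.6 FPKM (adjusted p = 0.0537, list adjusted p = 0.0713). Of 24 glycolysis and hypoxia genes 0 passed, also adjusted over the list alone, with P4ha1 at 76.9 ± 2.76 against 86.3 ± 4.05 FPKM (adjusted p = 0.144, list adjusted p = 0.909). Of 31 nuclear oxidative phosphorylation genes 1 fell, 0 rose and 30 did not pass, also adjusted over the list alone. It was Ndufa1, from 37.0 ± 1.26 to 31.0 ± 1.08 FPKM (adjusted p = 0.0293, list adjusted p = 0.445). Of 13 mitochondrially encoded genes 0 passed, also adjusted over the list alone, with mt-Nd3 at 8.36 ± 1.58 against 11.2 ± 2.2 FPKM (adjusted p = 0.389). Of the 50-base stretches of mt-Nd3, 98% also occur in another gene, so its level is uncertain. For the list members mt-Co2, mt-Co3 and mt-Atp6 these shares were 100%, 99.9% and 99.5%, so their levels are uncertain too. The median of the mitochondrial list was 0.02 while camera gave the downward direction (adjusted p = 0.977). At an unadjusted p under 0.05, limma counted 10 cholesterol, 2 cell cycle, 7 lysosome, 2 antibody handling, 6 unfolded protein response, 6 NRF2, 4 glycolysis and 0 mitochondrial genes. Limma-voom on recovered reads called 3, 0, 1, 1, 1, 1, 0 and 0 of these lists' genes in the same order.

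Beyond Fam107a, Hspb1 and Fkbp5, the genes with the largest falls on the log2(FPKM + 1) scale, by the naming rule, were Arl4d, Ada, Cdo1, S100a7a and Fam46b. The small GTPase gene Arl4d fell 2.09-fold to 1.98 ± 0.197 FPKM (adjusted p = 0.0125). Adenosine deaminase (Ada) fell 1.8-fold from 12.4 ± 1.33 to 6.88 ± 1.07 FPKM (adjusted p = 0.0149), and cysteine dioxygenase (Cdo1) fell 1.69-fold to 3.32 ± 0.227 FPKM (adjusted p = 0.00435). S100a7a and Fam46b fell 1.57- and 1.58-fold, with adjusted p of 0.0446 and 0.00592. Fam107a itself lies on chromosome 14 (8296274 to 8318023, minus strand) and had an adjusted p = 0.00435. Ccl6 lies on chromosome 11 (83587882 to 83593087, minus strand), and its adjusted p = 7.62e-06 was the smallest of the 12334 genes.

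All 12 list calls, 10 upward and 2 downward, were made with a preset correlation between genes, and 0 of them held with a correlation estimated from these 6 libraries, where 2 lists had an unadjusted p under 0.05. The test for movement of a list in 1 direction (fry) called 1 list, the interferon-stimulated genes. The authors' deposited table marks 110 genes as up and 42 as down by a log2 fold change of at least 1 and an unadjusted p under 0.05, and 78 of these 152 have an adjusted p under 0.05 there. Of the 258 genes changed here, 235 have an adjusted p under 0.05 in the authors' deposited table, all 235 in the same direction. Among the genes fitted here, 390 have an adjusted p under 0.05 in that table, so some of its genes were not called here. Both comparisons use the same 6 libraries and are not independent.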

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

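Limma-voom on recovered reads, limma without robust variance estimation, voom with quantile normalization and the principal component settings were chosen after the data were seen. The 258 changed genes became 244, 178, 231, 235 and 250 under median scaling, no trend, no filter, a mean of at least 10 FPKM and a pseudocount of 0.1, of which 228, 164, 220, 148 and 249 were among the 258. With the stricter filter 59.6% of calls were higher, against 69.8%. The counts were 264 without robust variance, 488 with limma-voom on recovered reads and 485 with quantile normalization added, and 243, 235 and 232 of these were shared. Leaving out 1 library gave 55 to 390 genes, 11 to 32 interferon-stimulated genes and 11 to 15 lists. The interferon count of 27 fell to 16 with the stricter filter, which tested 19 of the 34 members, and stood at 25 to 32 in the other settings with all libraries. Aqp4 kept a log2 fold change of 0.33 without the trend but not its call (adjusted p = 0.0611). With 1 library left out it ranged from 0.28 to 0.38 and the adjusted p from 0.00391 to 0.107. The cause was not tested beyond the smaller number of libraries. Of the 12 list calls, 0 held with an estimated correlation, 1 with fry in 1 direction, and 19 lists passed fry's mixed test. The list mitochondrially encoded genes, not called and in camera directed downward with all libraries, was called upward without AQP4-IgG 1 (adjusted p = 0.0108) and had an adjusted p of 0.904 without Control-IgG 2. AQP4-IgG 1 had the lowest level of that list in its group, -0.254 against 0.06 and 0.239 in AQP4-IgG 2 and 3. The cause was not tested. The first principal component held 42.6% of the variance, and 42.4%, 38.2%, 55.7% and 38.3% under median scaling, no filter, the stricter filter and a pseudocount of 0.1. None of the 46 named calls changed sign in any setting, and 19 (without Control-IgG 2) to 45 (median scaling) were kept among settings that fitted all 46.

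The replicate numbers were not used as a block in the main fit, as fixed beforehand, since no batch, litter or day is given. The deviations of same-numbered libraries correlated at 0.20, 0.01 and 0.20. Those of differently numbered libraries correlated at -0.268 to 0.082, so a pairing stays open. With the number as a replicate block, 607 genes passed, 254 of them among the 258, and C3, Lcn2, Ccl2 and Cxcl10 passed with adjusted p of 0.0344, 0.0179, 0.0417 and 0.00227. Not every library correlated best with its own number: AQP4-IgG 2 did so with Control-IgG 1 (0.07). The test on simulated data recovered 66% of the smallest changes, so some changes of that size can go uncalled. The simulation gave every gene the same dispersion, so larger changes of genes with a wider spread can go uncalled too. C3, at a 3.46-fold ratio of group means, did not pass the main test.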

Other observations

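Some tests here were written down before their result was seen. They covered glucocorticoid targets not yet looked at, the median of seen targets without each library, and the microglia excess in libraries numbered 1. For the first of these, the comparison with the spread was added later. Glul and Sesn1 among those targets also stand in lists fixed beforehand (log2 fold changes -0.011 and -0.005), so that set was not wholly unseen. All other genes and tests here were chosen after the data had been seen. Outside the lists, some protease and chemokine genes rose. The metalloproteinase gene Mmp12 rose 4.59-fold from 0.627 ± 0.0108 to 2.88 ± 0.0662 FPKM (adjusted p = 0.000229). The chemokines Ccl12 and Ccl9 rose 1.79- and 1.33-fold (adjusted p = 0.00418 and 0.0307), Ccl17 2.3-fold (adjusted p = 0.0301), and Pf4 and Ppbp 1.72- and 4.09-fold (adjusted p = 0.0445 and 0.0113). The scavenger receptor Marco rose 2-fold to 2.77 ± 0.235 FPKM (adjusted p = 0.0284). No test was made of these genes as a group, and of the 23 microglia and macrophage markers 0 rose in limma over all genes, 1 rose adjusted over the list alone and 1 rose in limma-voom with quantile normalization. Among abundant markers C1qa averaged 83.7 ± 2.53 against 97.6 ± 16.2 FPKM and Ctss 73.4 ± 2.94 against 81.7 ± 11.6 FPKM (adjusted p = 0.501 and 0.608). The membrane restriction factor Ifitm3 rose from 313 ± 52.3 to 579 ± 46.7 FPKM (adjusted p = 0.0221), and the guanylate-binding proteins Gbp2 and Gbp9 rose 2.81- and 2.84-fold (adjusted p = 0.0267 and 0.00435).

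Some cytoskeletal genes were lower. In a list of 30 actin and serum response factor genes, written after calls in it had been seen and so not independent evidence, 9 fell, 29 had a negative fold change and 25 lay lower in all 3 AQP4-IgG libraries. The median log2 fold change was -0.17, and -0.18 and -0.15 under median scaling and quantile normalization. Lims2 fell from 16.9 ± 0.443 to 11.1 ± 0.669 FPKM (adjusted p = 0.00418) and Tns1 from 23.6 ± 1.63 to 17.2 ± 0.355 FPKM (adjusted p = 0.00822). Actb averaged 1362 ± 48.5 against 1560 ± 37.0 FPKM (adjusted p = 0.0579). Acta2, Tagln and Cnn1 also stand among the fibroblast, meningeal and mural markers, a list that fell in camera with the preset correlation (adjusted p = 0.00195) but not with an estimated one (adjusted p = 0.304), and a lower share of contractile cells was not tested for.

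The rise of interferon-stimulated genes was weighed against 3 technical explanations. A larger share of microglia in the AQP4-IgG libraries is argued against by the microglia list. Its median log2 fold change was -0.035 with an upper quartile of 0.041, below the lower quartile of 0.748 of the interferon list. Whether the microglia present responded themselves was not tested. Scaling by the authors is argued against because 1 factor per library moves all genes alike, while the median of the interferon list lies 1.045 above that of all 12334 genes, whose quartiles were -0.056 and 0.061. A contaminant of the IgG preparation such as endotoxin, acting in place of AQP4 binding, cannot be told apart from the antibody, since preparation and antibody coincide in the design and the NF-kB list also rose in its median (0.468). Of the 10 splits of the 6 samples, 1 gave as many changed genes, the real one with 258 against 0 for the highest of the others, and 10 splits are too few for a share under 0.05. The other splits mix the groups, so the group difference widens their spread and their count of 0 does not measure chance. With Control-IgG 1 in place of AQP4-IgG 3, 1294 genes had an unadjusted p under 0.05 in limma, against 1643 in the real split.

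Among glucocorticoid-responsive genes, 8 of a list of 21 known targets whose values had been seen fell, with a median of -0.357: Fkbp5, Tsc22d3 (10.03 ± 0.712 against 15.5 ± 0.761 FPKM, adjusted p = 0.00435), Sgk1 (49.7 ± 2.33 against 69.4 ± 3.5 FPKM, adjusted p = 0.00435) and Klf15 (adjusted p = 0.0095) were among them. The microglia list cannot decide whether fewer microglia are behind this. Its median of -0.035 lies 0.323 above that of the targets, more than its interquartile range of 0.278. These targets were listed after their values were seen, however, which can widen the gap. Fewer fibroblast-like or mural cells cannot be told apart, since the median of their list, -0.071, lies 0.286 above with a range of 0.316. In that list Acta2 fell, while Col1a1 and Pdgfrb had log2 fold changes of -0.05 and -0.003. Whether a single library decides the pattern stays open, since these targets were listed after their values had been seen and the 13 of 21 that lie lower in all 3 AQP4-IgG libraries include the called ones by construction, so that the test written beforehand, a median below 0 without each library (-0.361 to -0.292), could not have failed. A set of 24 further targets did not fall by the size seen. Their median of -0.018 lies 0.339 above that of the seen targets, more than their interquartile range of 0.152. Limma called 0 of them lower, limma-voom with quantile normalization called 2 of 22, and fry in 1 direction gave an unadjusted p of 0.128. Of the 24, 15 had a negative fold change and 5 lay lower in all 3 AQP4-IgG libraries, while Angptl4 lay higher. This gap cannot decide on a fall in general, since the seen targets were listed after their values were seen. A smaller fall stays open, since for the 24 targets camera gave an unadjusted p of 0.0404 with the preset and 0.231 with an estimated correlation.

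NF-kB-induced genes also varied within groups. In 23 of 29 list members (79.3%) the library numbered 1 was the highest of both groups, where chance gives 11.1%, and if such genes move as a single program that 11.1% also holds for the list as a whole. This share restates what prompted the test, so a culture or day shared by the libraries numbered 1, which the labels do not name, stays open. More microglia in these libraries cannot be told apart either: the microglia list exceeded the other libraries by 0.32 log2 units in Control-IgG 1 and by 0.145 in AQP4-IgG 1, against 0.469 and 0.235 for the NF-kB list, with lower quartiles of 0.249 and 0.142. The excess was not particular to NF-kB-induced genes: for the interferon list it was 0.458 in Control-IgG 1 and 0.169 in AQP4-IgG 1. No biological explanation was tested.

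A few values stand out among genes that share sequence with other genes; whether shared reads are behind them was not tested. Gapdh is listed at 4.64, 28.6 and 5.53 FPKM in AQP4-IgG 1 to 3 and at 1.78, 2.9 and 2.11 FPKM in Control-IgG 1 to 3, and 24.7% of its 50-base stretches occur in 218 other genes. Among mitochondrial genes, mt-Co1, with 51.1% of its stretches also found elsewhere, averaged 7315 ± 562 and 7145 ± 402 FPKM, while mt-Co2, with 100%, averaged 26.1 ± 2.53 and 29.6 ± 7.44 FPKM. For mt-Cytb, with 0%, the libraries ranged from 3094 to 4223 FPKM. They ranged from 18.8 to 85.9 FPKM for mt-Co3 (99.9%), with the highest value in AQP4-IgG 3, and from 16.0 to 44.7 FPKM for mt-Atp6 (99.5%).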
